A study of Drosophila melanogaster with 3 samples.

How the data were processed

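Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster of the stage labelled 3dFemale, from the source labelled 7T, whose sample title names the transgene cad-GFP. Caudal, the product of cad, is a homeodomain transcription factor, and the GFP tag lets an anti-GFP antibody (labelled NWG-GFP) recover the chromatin it is bound to. Per the labels' protocols, the material was homogenised in formaldehyde, sonicated and incubated with the antibody, protein A beads collected the bound chromatin, and an aliquot of the same extract served as input. The growth text in the labels describes an embryo collection, which does not match the stage label, so the stage is given here only as labelled. The series lists 3 samples. These are 1 ChIP sample, whose title covers replicates 1 and 2, and 2 input samples.

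The data analysed were 1 peak list, that of the ChIP sample. No values of the input samples were analysed here. Per the file headers, the peaks were called with MACS, and per the submitters' processing notes reads were aligned with Bowtie and the build was BDGP5. The versions and settings of these tools, and whether the reads of the ChIP replicates were pooled before calling, are not given in the sources used here. The list deposited by the authors gives each peak's sequence name, start, end, running number and a score. The running numbers had no gap from the first to the last of the 7579 peaks, and no peaks overlapped.

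The deposited score is not defined in the file. Its lowest value was 50, and 29 peaks shared the value 3100 exactly with 2 just above it, which is the pattern of minus 10 times the log10 of a p-value that starts at 1e-05 and stops at the limit of number storage. It was therefore used to order, select and describe peaks within this list, as a capped value on the scale of the authors, and was not read as an amount of binding. Differences and ratios of scores are on that scale only and are not folds of reads or of binding. The values of 31 peaks at or above 3100 cannot be ordered among themselves. The read depth is unknown, because the list holds neither read counts nor fold enrichments, so no depth-based interval or detection limit could be given for a peak or for a stretch without peaks. Such a score grows with the number of reads as well as with enrichment, and a deeper library would have moved more positions over the floor of 50.

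Starts are printed from 1, taking the deposited starts as the 0-based BED convention. A midpoint is the mean of start and end, and no summits were given. All positions are on BDGP5. The gene table used for names was of another release, so it was not used to place genes, and no genome sequence of BDGP5 was used here. For that reason the comparisons planned with gene positions, fixed gene lists and the Caudal motif were not run, and peaks are identified by position only.

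Before the data were examined, 3 comparisons that need no annotation were fixed. Peaks per chromosome arm were tested by an exact two-sided binomial test against the share of the summed spans (first peak to last peak) of all 14 sequences, with Benjamini-Hochberg adjustment over the 6 arms 2L, 2R, 3L, 3R, 4 and X. Spacing was tested as the number of neighbouring midpoints within 5 kb, against 1000 uniform placements of the same number of peaks within the span of each sequence (two-sided permutation test, smallest possible p 0.002). The relation of score and width was measured across peaks by Spearman's rho and by Pearson's r of the log10 values, each with 100000 permutations (smallest possible p 1e-05). Peaks are the units in these tests and there is no second list, so the p-values describe this list and not variation between animals or libraries. The rule for named positions took the 20 peaks of highest score, the 5 stretches of 100 kb with the most peaks and the longest peak-free stretch of each arm. The rule broke ties of score by position. Because peaks at the score cap share a value, all 31 at or above it were listed instead, which departs from the rule. A tie at the last count of peaks extended the stretches to 6. An adjusted p under 0.05 was called.

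Alternatives fixed beforehand were the 3789 peaks with the highest score, the 1000 peaks with the highest score, peaks merged within 500 bp, the 6 arms only, an arm length counted as 100 kb bins that hold a peak, neighbour distances of 2 kb and 10 kb, random placement in bins that hold a peak, and widths within the 5th to 95th percentile. Windows of 1 Mb as units, placement with widths and without overlap, placement within a peak's own 100 kb bin (also for merged peaks, with and without their widths and gaps kept), the spacing test on each arm alone, and the removal of peaks at the score cap were added after seeing the data. The tests were tried on simulated lists of 7556 peaks. The arm test called at least 1 arm in 4 of 100 lists without a difference. It called X in 100 of 100 lists in which X was raised 1.2-fold and 30% of the peaks were also moved next to another peak. Those peaks were clustered, so the 100 of 100 does not measure the power of the arm test for independent peaks. All simulated peaks lay on the 6 arms, and the lists without a difference had peaks placed independently, as the binomial test assumes. The 4 of 100 is therefore no rate of false calls for a list whose peaks cluster. The spacing test called 1 of 100 uniform lists. It called 100 of 100 of the same lists with X raised and 30% of the peaks moved next to another peak. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.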

Results

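The peak list of the cad-GFP ChIP sample at the stage labelled 3dFemale held 7579 peaks on 14 sequences of the BDGP5 assembly. Whether Caudal was bound at each of them was not tested. Caudal is a homeodomain transcription factor known for posterior patterning of the embryo and for its role in the intestine. The 6 chromosome arms carried 7556 of the peaks (99.7%), and 23 lay on 8 other sequences. No peak lay on a sequence named for the Y. The peaks together covered 13.5 Mb, and on the arms they covered 11.4% of the span from the first to the last peak. The median width was 1366 bp, with quartiles of 873 and 2190 bp and a range of 155 to 15741 bp. The median score was 198.7, with quartiles of 102.0 and 417 and a range from the floor of 50 to 3145.59. Scores under 100 were held by 1829 peaks (24.1%) and scores of 1000 or more by 513 peaks (6.77%). One list stands for the ChIP replicates, so no value below has a replicate error, and the depth of reads behind the peaks is unknown.

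The first comparison asked how the peaks were shared among the chromosome arms. Arm 2R was the most densely occupied, with 1524 peaks or 72.8 per Mb of span, and chromosome 4 the least, with 34 peaks or 29.7 per Mb. Arm 2L, with 1281 peaks, had 56.0 per Mb. The X held 1381 peaks (61.7 per Mb), 3R held 1788 (64.1 per Mb) and 3L held 1548 (66.5 per Mb). The share of the span inside a peak followed the same extremes, from 4.52% on chromosome 4 and 9.95% on 2L to 13.2% on 2R.

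Chromosome 4, the small arm that is known to be rich in heterochromatin, held 0.57 times the number of peaks expected from its part of the summed spans of all 14 sequences (exact binomial test, adjusted p = 0.00042). By the same exact test, 2R held 1.39 times its expected number (adjusted p = 5.18e-39), 3L 1.27 times (2.74e-22), 3R 1.22 times (1.03e-19), X 1.17 times (2.90e-10) and 2L 1.07 times (adjusted p = 0.0124). These ratios depend on Uextra, a set of unplaced sequence that made up 13.3% of the summed spans and held 4 peaks. In the exact test against the spans of the 6 arms alone, 2R stayed above its share (1.14 times, adjusted p = 1.30e-07), chromosome 4 stayed below it (0.47 times, 9.97e-07), and 2L was now below it (0.88 times, 5.35e-07). With that denominator the exact test did not call 3L (1.04 times, adjusted p = 0.102), 3R (1.01 times, 0.786) or X (0.97 times, 0.212). The exact test treats peaks as independent, but 44.7% of neighbouring midpoints lay within 5 kb, against 27.5% in random placements. Its p-values with either denominator are therefore too small, by an amount that was not estimated.

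The number of peaks varied widely along each large arm. In complete windows of 1 Mb, 2R held 73.2 ± 22.8 peaks (SD, n = 20 windows), 3L 67.1 ± 18.2 (n = 23), 3R 64.4 ± 16.7 (n = 27), X 62.5 ± 17.9 (n = 22) and 2L 57.6 ± 19.6 (n = 22). With these windows as units and their arm labels permuted, none of the 5 large arms passed the threshold. The unadjusted permutation p was 0.032 for 2R and 0.052 for 2L, and both were 0.129 after adjustment. The span of chromosome 4 holds only 1 such window. The density of this chromosome was reached or undercut by 3 of the 114 windows of the large arms, where the mean was 64.8 ± 19.3 (SD). No test of its peak number that allows for clustering was run.

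**Figure D1:**
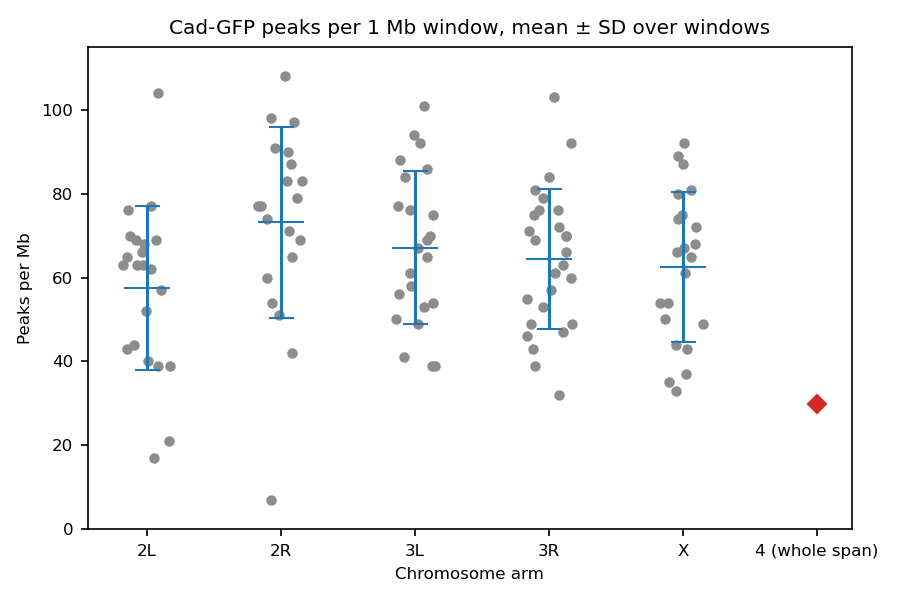
Peaks per 1 Mb window (y axis) for the 5 large chromosome arms, with each window as a grey point and the mean ± SD over windows in blue; the red diamond is chromosome 4, counted over its whole span. The windows of each large arm overlap those of the others, and chromosome 4 sits at 29.7 peaks per Mb.

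The second comparison asked whether the peaks were spread evenly along the arms. They were not. Of the 7565 neighbouring pairs, 3380 (44.7%) had midpoints within 5 kb of each other, where random placement gave a mean of 2079 (27.5%) and a central 95% range of 2015 to 2144. The ratio was 1.63 (permutation test, p = 0.002, the smallest that 1000 placements can give). The share of neighbours within 5 kb was 43.1% on 2L against 24.4% in random placements of its own peaks, 46.5% on 2R against 30.5%, 47.3% on 3L against 28.21%, 42.4% on 3R against 27.4% and 44.9% on X against 26.5%. The ratios on these arms were 1.77, 1.53, 1.67, 1.55 and 1.69 (permutation tests, adjusted p = 0.0024 for each over 6 arms). On chromosome 4 the share was 24.2% (8 of 33 pairs) against 14.1% at random, a ratio of 1.72 that did not pass the threshold (permutation test, adjusted p = 0.124), and the ratios were not tested against each other. Among the 1000 peaks with the highest score, 57 neighbouring pairs lay within 5 kb against 44.0 expected, which did not pass the threshold (permutation p = 0.060). Part of the closeness came from peaks that nearly touch, since 471 pairs (6.23%) had edges 100 bp or less apart. With peaks merged across gaps of up to 500 bp the ratio was 1.25 over 6242 merged peaks (permutation p = 0.002). With merged peaks placed at random within their own 100 kb bin, and widths and gaps of over 500 bp kept as in the merged list, 1804 pairs stood against a mean of 1184 (ratio 1.52, permutation p = 0.002). Placement of their midpoints alone gave a ratio of 1.00 (permutation p = 0.885), but it allows the short distances that merging removes from the list, which raises the random count by construction.

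**Figure D2:**
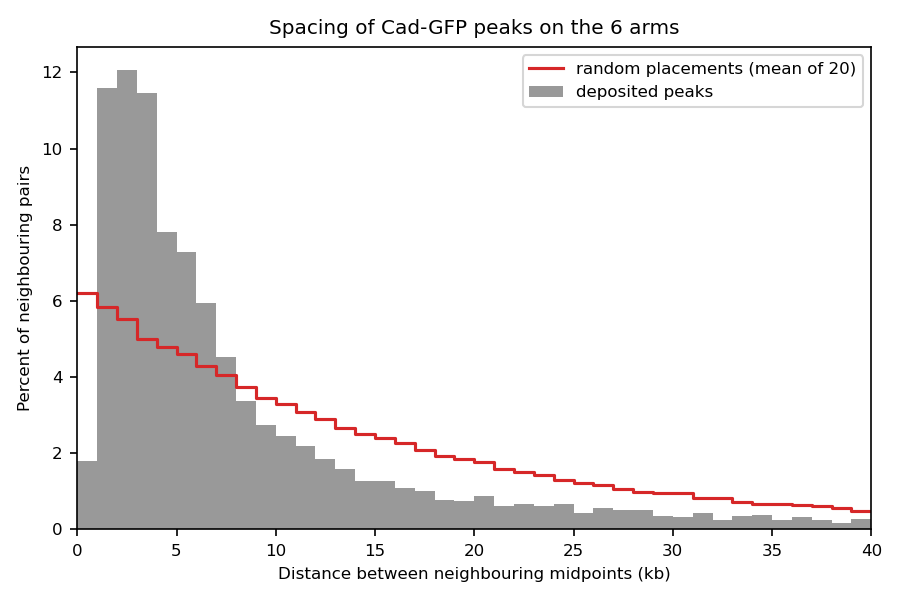
Distance between the midpoints of neighbouring peaks on the 6 arms (x axis, kb) against the percent of neighbouring pairs (y axis), as grey bars for the deposited peaks and as a red line for the mean of 20 random placements. The deposited peaks exceed the line at a few kb, and 8.66% of their pairs lie beyond the 40 kb shown.

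The densest stretches lay on 2R, 3L, 3R and X. The stretch 2R 7500001 to 7600000 held 24 peaks covering 44748 bp, and 3L 17900001 to 18000000 held 22. Each of 2R 3600001 to 3700000, 3L 7800001 to 7900000, 3R 21100001 to 21200000 and X 13200001 to 13300000 held 21 peaks, the last covering 42036 bp. In all, 12 stretches of 100 kb held 20 or more peaks. Random placement gave a mean of 0.023 such stretches, and its fullest stretch held 16.5 peaks on average, with a central 95% range up to 19. The fullest stretch held 15 peaks when only the 3789 peaks of highest score were kept (random range 9 to 13), and 6 among the 1000 of highest score, within the random range of 4 to 7. The median score of the peaks was 143.76 in the fullest stretch of 2R, 123.0 in that of 3L and 176.5 in that of 3R, under the 198.7 of the whole list. It was 250.1 in the other stretch of 2R, 243.8 in that of 3L and 303 in that of X. Within the fullest stretch, 18 consecutive peaks from 7524432 to 7569191 on 2R followed each other at no more than 5 kb between midpoints, the longest such run in the list. The next was a run of 16 peaks on 3R from 16995148 to 17027126.

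Stretches without any peak were also more frequent than under an even spread. Of the 1190 stretches of 100 kb within the arm spans, 148 (12.4%) had no peak midpoint, where random placement left 4.25 empty on average and at most 8 in its central 95% range. Empty stretches numbered 252 for the 3789 peaks of highest score (random range 43 to 69) and 607 for the 1000 of highest score (498 to 537). The share of empty stretches was 16.2% on 2L, 13.8% on X, 12.2% on 3R, 11.1% on 3L and 9.52% on 2R, and chromosome 4 had 0 of 13. The longest peak-free interval of the list was on 2L, from 16910671 to 17378619 (468 kb). On X it ran from 11923436 to 12356296 (433 kb), on 3L from 13507403 to 13855289 (348 kb), on 3R from 1834451 to 2176236 (342 kb) and on 2R from 703680 to 1009391 (306 kb). Each of these 5 was longer than the longest interval in any of 1000 random placements of its arm (one-sided permutation p = 0.001, the smallest possible). On chromosome 4 the longest, 718606 to 827479 (109 kb), was not (permutation p = 0.738). Whether reads could be mapped in these intervals was not tested here.

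**Figure D3:**
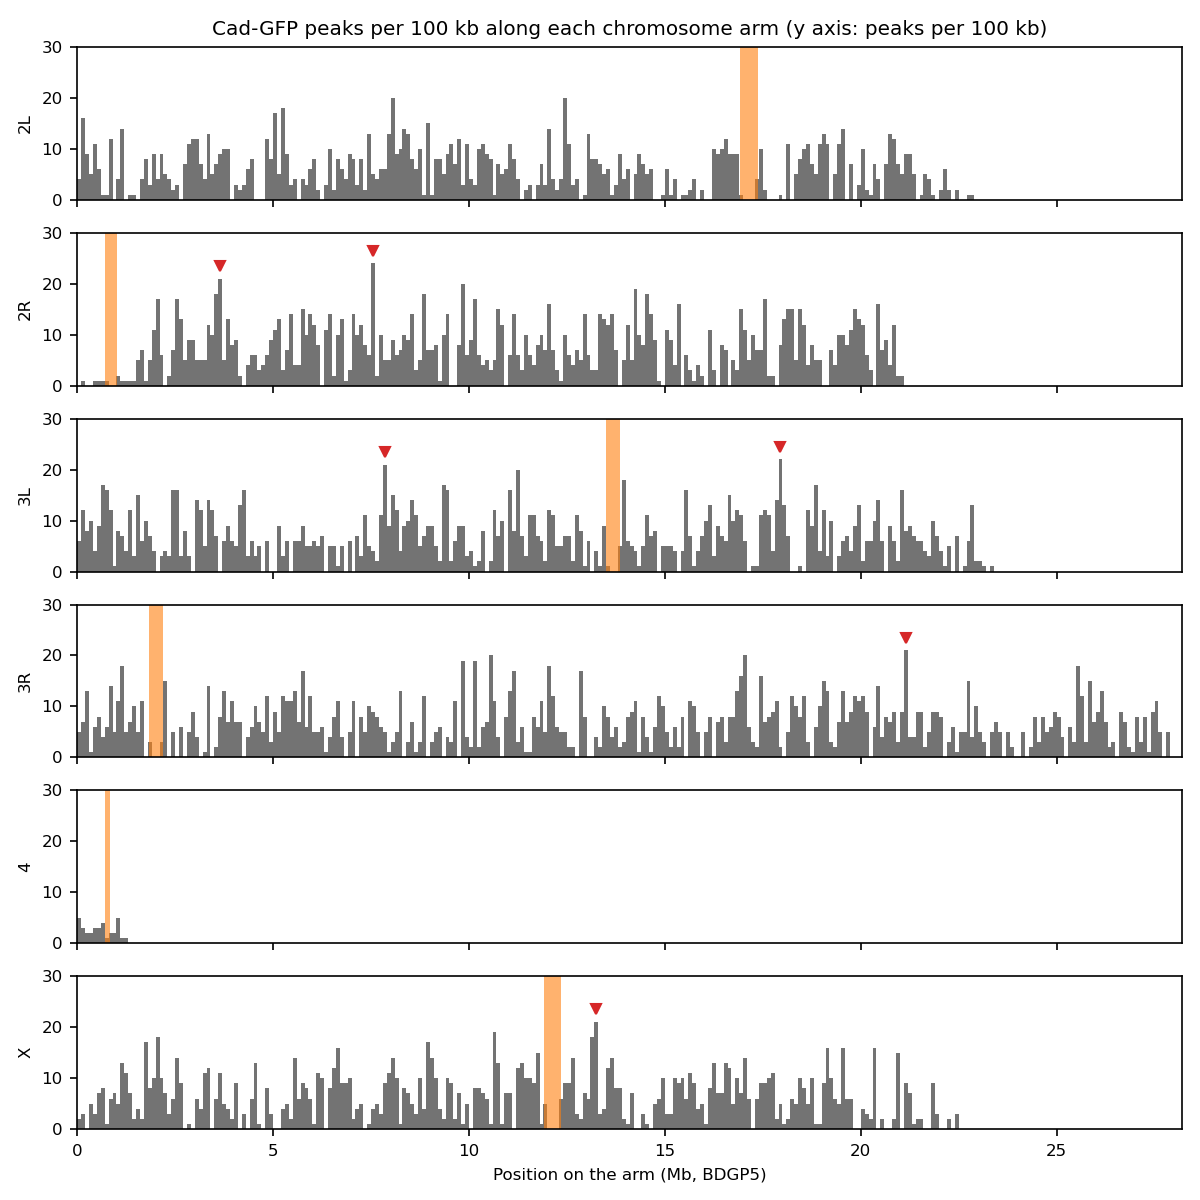
Number of peaks per 100 kb (y axis) along the 6 chromosome arms (x axis, Mb on BDGP5), with red triangles over the 6 fullest stretches and orange bands on the longest peak-free interval of each arm. The fullest stretch, on 2R, holds 24 peaks, and the widest band, on 2L, spans 468 kb.

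The third comparison set the score of a peak against its width. Wide peaks had high scores. The median score was 93.9 for peaks of 155 to 873 bp, 158.35 for 874 to 1366 bp, 253.4 for 1367 to 2190 bp and 546 for 2191 to 15741 bp, classes of 1893 to 1898 peaks each. Across the 7579 peaks Spearman's rho was 0.66 and Pearson's r of the log10 values was 0.68 (permutation p = 1e-05 for each, the smallest possible, peaks of 1 list not being independent replicates). Within arms rho ran from 0.63 on chromosome 4 to 0.69 on X. Score and width came from the same peak call on the same reads, so they are not independent measures. The permutation test cannot separate a relation that the calling itself gives from one in the binding. Of the 10 widest peaks, 3 had reached the score cap. The widest of all, X 8372647 to 8388387, had a score of 1369.9.

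The strongest peaks could not be ranked beyond the cap. The single highest values were 3145.59 for the peak at 2L 476619 to 486920, which was 10302 bp wide, and 3140.95 for that at 2R 5313715 to 5320834, 7120 bp wide. The other 29 shared the value 3100. On 2L these were the peaks starting at 2195608, 2749101, 3301072, 12009506 and 14612158, and the one at 3301072 to 3303860 was the narrowest of the group at 2789 bp. On 2R they started at 2513946, 4030004, 5069981, 7088887, 8054540, 16882225 and 19599197. On 3L they started at 9411377, 9682029 and 14747857, of which the first, ending at 9424686, was the widest of the group at 13310 bp. On 3R they started at 4871972 and 17121319. The X held 12, starting at 2191407, 3632922, 7597302, 7983839, 9475621, 11317036, 11708586, 12552050, 12627431, 12643496, 14959199 and 19387971, so that 3 of them fell within 12552050 to 12648519. The median width of the 31 peaks was 7169 bp.

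**Figure D4:**
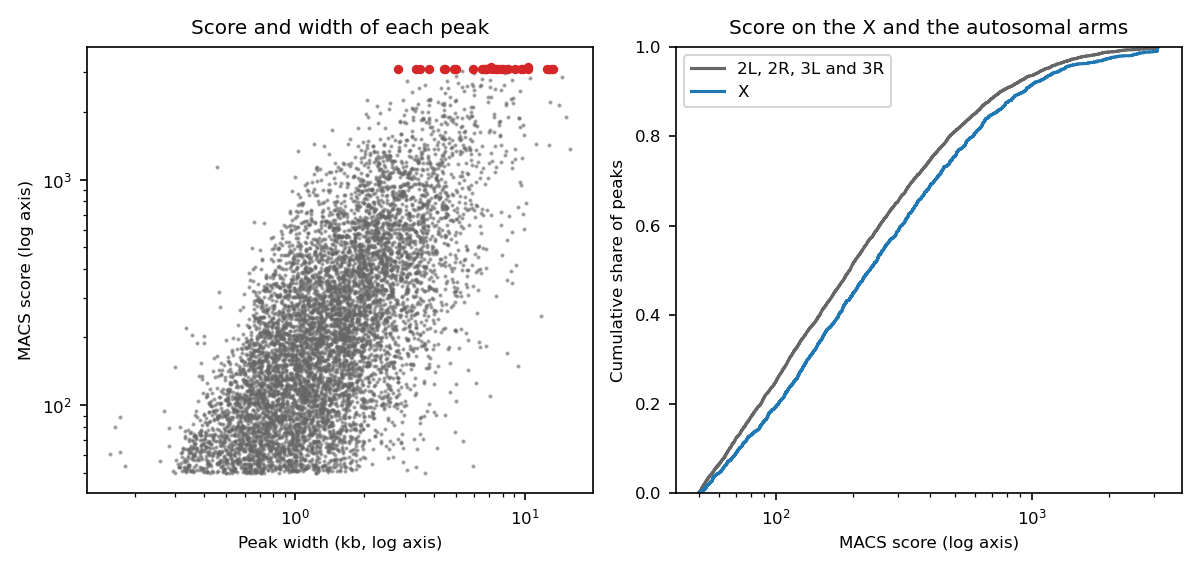
Left, MACS score (y axis, log) against width (x axis, kb, log) of each of the 7579 peaks, with the 31 peaks at or above the score cap of 3100 in red. Right, cumulative share of peaks (y axis) by score (x axis, log) for the X in blue and for 2L, 2R, 3L and 3R together in grey; the median is 232 on the X and 194.8 on the autosomal arms.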

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

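The 23 peaks outside the chromosome arms (0.303% of the list) entered no comparison of their own and were set apart as signal outside the main measurement. The sequence named XHet held 7 of them, all between 46669 and 76889, a stretch of 30.2 kb, with widths of 501 to 825 bp and scores of 52.14 to 303.11. The highest score outside the arms, 1132.11, belonged to a peak of 456 bp at Uextra 5224012 to 5224467. The other peaks of Uextra and those of U scored from 53.59 to 210.29, and the 3 on U were 155 to 180 bp wide. One peak on the mitochondrial genome, at 4530 to 4796, had a score of 94.16. No input peaks were analysed here, so these peaks were not compared here with a control. The settings of the peak caller are not given, so whether the input entered these scores is unknown.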

How the results depend on the processing

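The count of called arms was 6 against the spans of all 14 sequences, 3 with the arms only, 3 with lengths counted as 100 kb bins holding a peak, 1 among the 1000 peaks of highest score, 5 among the 3789 peaks of highest score (X 1.0955 and 3L 1.07 still called), 6 after merging, and 0 of 5 with 1 Mb windows as units (chosen after seeing the data; 1 arm, 2R, had an unadjusted p under 0.05). Arm 2L reversed, from 1.07 times its expected number to 0.91 among the 3789 peaks of highest score, 0.78 among the top 1000, 0.88 with arms only, 0.93 with occupied bins and 0.87 with windows. X reversed to 0.97, 0.99 and 0.96 in the last 3 of these settings and was 1.16 among the top 1000 (not called). In both score subsets the spans were measured again from the peaks kept, so the peaks and the denominator changed together. Of the top 1000, 999 lay on the arms, so their ratios compare with those of arms only, where 2L was already below its share. For 3R the ratio was 1.01 among the 3789 peaks, 0.95 among the top 1000, 1.01 with arms only, 1.02 with bins and 0.99 with windows, and for 3L it was 1.04 among the top 1000, 1.04 with arms only, 1.04 with bins and 1.05 with windows, none of these called. Arm 2R kept its direction but not its call at 1.104 (top 1000) and 1.16 (windows). Chromosome 4 was not called at 0.67 (top 1000). It held 1 peak of score 1000 or more and its 95th percentile of score was 581, so few of its peaks entered that subset. Its span was measured again from those few, so the 0.67 decides nothing about its direction. Except with windows as units, the arm calls rest on the exact test, whose p-values are too small for peaks that cluster. The low density of Uextra in the denominator raises every arm by construction. Much of its span drops out of the score subsets, since only its peaks of 210.29 and 1132.11 score above the list median of 198.7. Part of the fall of the ratios in those subsets therefore follows from the denominator, and the effect of score alone was not tested. The spacing ratio lay above 1 in all 11 alternatives and kept its call in 9 (1.11 to 2.15); it was not called among the top 1000 (1.30) or for merged midpoints placed in their own 100 kb bin (1.003, added after seeing the data), where the placement allows distances that merging removes; with widths and gaps kept it was 1.52. Score and width stayed related in all 6 alternatives (rho 0.42 to 0.68). Merging within 500 bp left 149 empty stretches of 100 kb (4 to 14 at random) and 19 peaks in the fullest (13 to 17); fewer peaks gave 252 and 607 empty and 15 and 6 in the fullest (3789 and 1000 peaks). The planned tests on gene positions, gene lists and the Caudal motif were not run, and leaving out a replicate was not possible with 1 list. The unknown depth leaves open whether empty stretches lack binding or reads.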

Other observations

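Except for the merging of peaks within 500 bp, the tests in this part were chosen after the data had been seen. Peaks on the X scored higher than those on the autosomal arms. The median score was 232 on X, against 195.5 on 2L, 184.4 on 2R, 198.9 on 3L and 197.5 on 3R, and 232 against 194.8 for the 4 autosomal arms together (permutation p = 1e-04, the smallest possible). The X held 117 of its 1381 peaks at a score of 1000 or more (8.47%, exact 95% binomial interval 7.06 to 10.1%), against 395 of 6175 (6.40%) on the other arms (Fisher's exact test, odds ratio 1.35, adjusted p = 0.040 over 10 tests), and 12 of the 31 peaks at the score cap (odds ratio 2.84, adjusted p = 0.040). In windows of 1 Mb, the mean of the median scores was 241 ± 50.9 on X (SD, n = 22) and 196.9 ± 36.0 on the autosomal arms (n = 92), and 19 of the 22 windows of X lay above the autosomal mean. The centromere-side ends of 4 of the 5 large arms held fewer peaks than the arm mean. The last 1 Mb of 2L, 3L and X held 14, 33 and 21 peaks and the first 1 Mb of 2R held 7, against arm means of 57.6, 67.1, 62.5 and 73.2, while the first 1 Mb of 3R held 69. Within 2 Mb of those ends of the 5 large arms, 22 of 100 stretches of 100 kb had no peak (22%), against 126 of 1077 (11.7%) in the rest; this difference was not tested. The arms were unlike in this: 8 of the 22 lay on X and 2 on 3R, where the first 1 Mb was not sparse. The telomere-side 1 Mb was below the arm mean on X (43 peaks against 62.5), 3R (51 against 64.4) and 2R (63 against 73.2), and above it on 2L (65) and 3L (101).

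For the higher scores on the X, greater width does not account for the whole of the shift, because the X median was 1.11 times the 209 expected at matched width, above the central 95% range of 198.5 to 220 (permutation p = 0.0002). A few unusual stretches do not account for it either, since with windows as units the difference remained 44.4 score units (permutation p = 3e-05). For the peaks of 1000 or more alone, the excess was 1.15 times at matched width (permutation p = 0.071) and 1.16 times when each 100 kb stretch was counted once (permutation p = 0.058), so width and repeated counting stay open for that part. Neither check was run for the peaks at the score cap, whose median width was 7169 bp, so both stay open there too. A higher number of reads on the X may raise scores there. The X had 0.96 times as many peaks per window (95% bootstrap interval 0.84 to 1.08), which decides nothing, and without read counts this cannot be told apart from stronger binding, which was not tested.

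For the close spacing of peaks, splitting of enriched stretches by the peak caller at gaps of up to 500 bp does not alone account for the whole excess. Merging peaks within 500 bp left a ratio of 1.25 (1804 pairs against 1445 expected, the highest of 1000 placements being 1530). Splitting at wider gaps was not tested. Differences in peak density between 100 kb stretches do not alone account for it either: with each peak placed within its own bin the ratio was 1.27. For both together the answer depended on the placement and is not settled here. Merged peaks placed within their own bin with widths and gaps kept gave a ratio of 1.52 (1804 pairs against 1184, the highest placement being 1262). No like value exists for the unmerged list, which was not placed in this way. Its 2.15 with widths and without overlap came from placement over whole spans without a smallest gap. It therefore differs from the 1.52 in more than merging. The 1.25 and 1.27 come from placements of midpoints and are on neither basis. The criterion set first also required an excess with midpoints alone, where the ratio was 1.003, and was dropped after both values were seen, because that placement allows distances that merging removes. Density differences over less than 100 kb, the position of genes and that of sequence to which reads cannot be mapped uniquely were not tested, and the design holds no second group that would give a biological explanation to test.

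Peaks close to each other had slightly similar scores. Over all 4103 pairs of peaks with midpoints within 5 kb, adjacent in the list or not, the rank correlation was 0.060 (permutation p = 0.001, adjusted p = 0.004 over 4 distance classes), and at 5 to 10 kb it was 0.023 (adjusted p = 0.249). The pairs within 5 kb include peaks that nearly touch. The correlation was not repeated on merged peaks, so whether split stretches produced it was not tested. At 20 to 50 kb it was 0.0084 (permutation test, adjusted p = 0.411), under the level set for differences in depth or copy number over long stretches. That level was a chosen fraction of the value within 5 kb. Without read counts, the correlation that such differences would give is unknown, so they are not excluded. The hypothesis that peaks in crowded surroundings score higher was not borne out at the size set for it, 0.1: the rank correlation of the score with the number of other peaks within 25 kb was 0.027 over 7556 peaks (permutation p = 0.021).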
